A study of Mus musculus with 2 samples.

How the data were processed

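Total RNA from the hearts of 2 male mice of the F1 hybrid strain B6CASTF1/J, aged 25 days, was sequenced as 2 libraries, 1 per animal, each from 300 ng of RNA per the labels. The labels number the libraries as biological replicates 1 and 2 and name animals 3 and 4 of a tissue bank, but give both the same donor identifier. They were treated here as 2 animals of 1 group. A set of synthetic spike-in RNAs for stranded, ribosomal RNA-reduced libraries was added per the labels. The labels name no second group, treatment, tissue or time point, so no comparison between groups was made.

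Estimated counts per gene, which need not be whole numbers because reads that match several genes are divided among them, were deposited by the authors in a gene table for each heart. TPM (abundance after division by effective length, scaled to the same total in each library) over all genes and spike-ins were deposited by the authors in the same table, as a maximum likelihood and as a posterior mean estimate. FPKM and posterior mean counts were deposited by the authors there too and were not analysed here. Each transcript's percent of its gene's abundance was deposited by the authors in a first transcript table, beside estimated counts and TPM. A second transcript table, with estimated counts and TPM, was derived directly from a read file, while the first tables were derived from an alignment to the transcriptome, per the text files the authors deposited with them. Those files name the genome assembly mm10 and the GENCODE annotation M21. The column names are those that RSEM writes in the first tables and kallisto in the second, and the tools, versions and settings are not given in the sources used here. In long transcripts, the deposited effective length was 99.0 bases (median) shorter than the length in the first table, and 332 (replicate 1) and 335 (replicate 2) shorter in the second. Short RNAs had high counts and TPM in the first quantification and almost none in the second, so their levels are uncertain, and the cause was not tested.

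Symbols, biotypes and coordinates were taken from the GENCODE M21 annotation by gene identifier. All 447 symbols fixed in advance were found, and for the 3 carried by more than 1 identifier (Aldoa, Atp5o and Rmrp) the identifier with the higher summed count was used. The gene table held 55536 genes, and 26248 transfer RNA rows, which summed to 3.0 and 1.85 counts in replicates 1 and 2 and were left out of library sizes, as were the spike-ins. Totals were 38447822 estimated counts in replicate 1 and 40891189 in replicate 2. A count of 0 allows up to 3 counts, or 0.0784 and 0.0738 CPM (counts scaled to the same total in each library) of the genes of replicates 1 and 2. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

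Pairs of isoform genes were compared within each heart as log2 of the ratio of TPM + 0.1, which understates ratios over genes near 0, and a pair was counted when the ratio lay above 0 in both hearts and the mean exceeded the SD. With 2 hearts an exact sign-flip test cannot go below a two-sided p of 0.5, so no p is given. Gene lists were summarised as the median over members of the mean TPM. For differences between the hearts, estimated counts were scaled by TMM factors (edgeR 4.0.16 in R 4.3.3, on counts rounded to whole numbers), genes at a mean of 1 CPM or more were kept, and genes differing by 2-fold or more were counted. There is 1 library per animal, so such a difference has no replicate test. It describes these 2 hearts. Ratios of named genes have exact binomial 95% intervals. A gene whose count rounded to 0 in a heart was set at 3 counts there, which gives a bound. List medians of the log2 ratio were ranked among 10000 random lists of the same size, matched on mean CPM in 20 bins, for lists with at least 3 members past the filter. The spread between hearts was the common dispersion of edgeR with an intercept alone, on rounded counts, given as a biological coefficient of variation. Transcript shares were percents of a gene's transcript TPM. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

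The steps were tested on simulated counts drawn from the real gene means and library sizes, with a coefficient of variation of 0.11, which was recovered as 0.1104 where no gene was changed and as 0.1411 with the changed genes in. Of 50 genes simulated at each fold size, the 2-fold threshold was passed by 2.0% at 1.5-fold, 56.0% at 2-fold, 98.0% at 3-fold and 100% at 4-fold. It was passed by 0.0473% of the 12693 unchanged genes. Every simulated gene had the same coefficient of variation and no reads were shared between genes, unlike in the real data. These rates are therefore not error rates of the real comparison.

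The lists, pairs, comparisons and alternatives were fixed before the data were examined, apart from what is named as chosen later, and so was the rule for the genes named. It takes the 15 genes of highest mean TPM, every isoform pair, the up to 4 highest and the 1 lowest member of each list, the 10 largest ratios each way between hearts, up to 4 members of a list that differed 2-fold or more, and all genes of the lists for sex and for transcripts. A few genes that the rule takes are not reported here. Genes outside the rule are marked as chosen after their values were seen. Alternatives were other units and pseudocounts, the second quantification, other scalings (DESeq2 1.42.0 size factors, library totals and spike-in totals), other filters and thresholds, and each heart left out.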

Results

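The data describe gene expression in the hearts of 2 young male mice at 25 days of age. Total RNA was sequenced, so that transcripts without a poly(A) tail, such as structural and mitochondrial ribosomal RNAs, were also counted. Replicate 1 held 38447822 and replicate 2 held 40891189 estimated counts. Values are means ± SD over both hearts (n = 2) unless a heart is named, and coordinates are those of the mm10 assembly. Both hearts had the transcripts of males, with Ddx3y at 19.8 ± 0.651 TPM, Eif2s3y at 20.4 ± 0.325, Uty at 7.37 ± 0.318 and Kdm5d at 3.56 ± 0.212 from the Y chromosome, and Xist, the RNA of the inactive X chromosome, at 0.020 ± 0.0141.

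Mitochondrial transcripts took 31.3% ± 0.490 of gene counts, and the mitochondrial ribosomal RNAs alone took 20.6% ± 0.871. The gene with the highest mean was mt-Rnr2, the large mitochondrial ribosomal RNA, at 129594 ± 7769 TPM, and mt-Rnr1, the small one, stood at 54979 ± 644. Among mitochondrial messenger RNAs the highest were mt-Co1 at 33784 ± 286, mt-Co3 at 17990 ± 279, mt-Atp6 at 15699 ± 1982, mt-Nd1 at 13363 ± 3877 and mt-Cytb at 13228 ± 1465, while mt-Co2 had the lowest level of the list, at 769 ± 25.4. Gm28661, Gm29216 and Gm10925 also ranked among the 15 highest, at 32519 ± 6661, 15326 ± 279 and 10376 ± 91.7 TPM. They belong to 7 unprocessed pseudogenes on chromosome 1 that are near-identical to mitochondrial genes, so that the split of reads between the 2 sets is uncertain. The ranking of the mitochondrial messenger RNAs, with the low level given to mt-Co2, is therefore uncertain too. Together these pseudogenes held 3.24% ± 0.355 of gene counts. The short RNAs Rn7s1 and Rn7s2, copies of the signal recognition particle RNA, each stood at 89186 ± 10206 TPM, and Rn7sk, a regulator of transcription elongation, at 15970 ± 137. In the second quantification the same RNAs had 0.711, 0.711 and 0.406 TPM, and all RNAs of their biotype together went from 3.40% to 1.98e-04% of gene counts, so their levels are uncertain. The hemoglobin genes Hbb-bs and Hba-a1 completed the 15, at 12619 ± 5938 and 10777 ± 4853 TPM, with SDs far larger relative to the mean than those of heart muscle genes. In all, 11819 genes reached a TPM of 1 in both hearts, of which 10906 code for protein. Spike-ins held 0.541% ± 0.0515 of all counts. Across the 43 spike-ins with 10 counts or more in both hearts, their log2 counts correlated with Pearson's r = 0.998 and Spearman's rho = 0.996 (across spike-ins, which are not independent replicates).

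Isoform levels were described in 18 pairs of genes for the same or a related protein. The first encodes an adult or muscle form, and the second a fetal, atrial, other muscle or non-muscle form. No younger sample was available, so the ratios do not measure maturation, and the mix of cells and chambers in the samples may enter them. The first member was higher in both hearts in 18 of 18 pairs, with mean log2 ratios from 1.21 to 11.86 and no SD above 0.63. The largest ratio was that of cardiac troponin I, Tnni3 (ENSMUSG00000035458.15, chromosome 7, 4518305 to 4524229), over Tnni1, the slow skeletal form of the fetal heart, at 3398 ± 112 against 0.820 ± 0.156 TPM (log2 ratio 11.86 ± 0.29). Myh6 (ENSMUSG00000040752.16, chromosome 14, 54941921 to 54966927), the alpha myosin heavy chain of the adult mouse heart, stood at 8557 ± 353 TPM and Myh7, the fetal beta chain, at 809 ± 48.4, a log2 ratio of 3.40 ± 0.03. Cardiac actin Actc1 exceeded skeletal actin Acta1 by 5.13 ± 0.63 and smooth muscle actin Acta2 by 6.06 ± 0.06 on the log2 scale. Ventricular light chains exceeded atrial ones, with 4.30 ± 0.25 for Myl2 over Myl7 and 3.48 ± 0.19 for Myl3 over Myl4. The cardiac calsequestrin Casq2 exceeded the skeletal Casq1 by 6.70 ± 0.41, and the L-type calcium channel gene Cacna1c exceeded the T-type Cacna1g by 3.47 ± 0.09.

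Metabolic pairs pointed the same way. Log2 ratios were 5.74 ± 0.09 for muscle over brain creatine kinase (Ckm and Ckb), 5.32 ± 0.03 for the insulin-responsive glucose transporter Slc2a4 over Slc2a1, and 3.19 ± 0.06 for Cpt1b over Cpt1a, the muscle and liver forms of the enzyme that admits fatty acids to mitochondria. Eno3 exceeded Eno1 by 4.06 ± 0.11, and Pgam2 exceeded Pgam1 by 3.17 ± 0.05. Muscle forms of cytochrome c oxidase subunits were higher as well, by 3.10 ± 0.02 for Cox6a2 over Cox6a1, 2.59 ± 0.14 for Cox8b over Cox8a and 1.36 ± 0.07 for Cox7a1 over Cox7a2. The smallest ratios also included 1.75 ± 0.03 for Ldhb over Ldha and 1.21 ± 0.13 for Hk2 over Hk1. The size of a ratio depends on the quantification more than on the heart: in the second quantification the log2 ratio was 2.06 for Myh6 over Myh7, 0.46 for Cox7a1 over Cox7a2, 4.97 for Myl2 over Myl7 and 2.47 for Ldhb over Ldha.

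**Figure D1:**
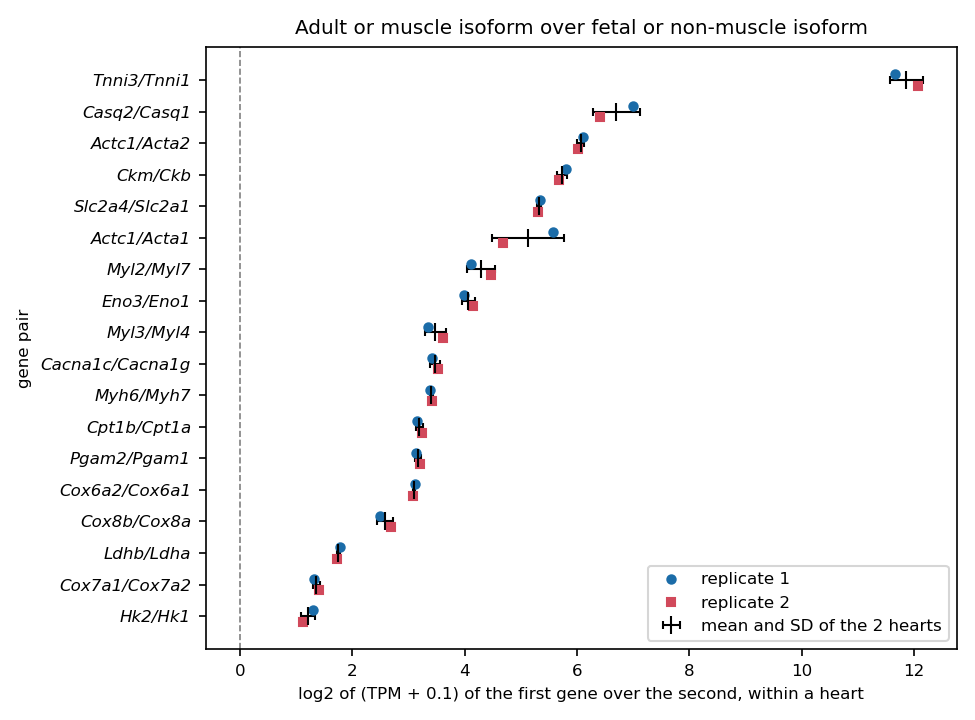
Log2 ratio of TPM + 0.1 of the first over the second gene of each pair, within each heart (circles, replicate 1; squares, replicate 2), with the mean and SD of both hearts as bars; the dashed line marks equal levels. All 18 pairs lie to the right of it in both hearts, from 1.21 for Hk2 over Hk1 to 11.86 for Tnni3 over Tnni1.

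The cell types in the samples were described with 24 lists of marker genes. Markers may also be expressed by other cells of the heart, so their levels need not come from the named cell type alone. Heart muscle cell markers had a median of 3218 TPM, with Myh6, Actc1 (5123 ± 973), Myl3 (4159 ± 226) and the calcium pump gene Atp2a2 (3801 ± 75.2) highest and the ryanodine receptor gene Ryr2 (344 ± 13.0) lowest. Both chambers were represented. The ventricular light chain Myl2 stood at 6110 ± 514 TPM and the ventricular transcription factor gene Irx4 at 8.26 ± 1.46, while the lowest ventricular markers were Hey2 (2.10 ± 0.0283) and Scn4b (0.810 ± 0.113). Atrial markers were led by Nppa, which encodes atrial natriuretic peptide, at 893 ± 11.1 TPM, Myl4 (373 ± 29.6), Myl7 (311 ± 27.7) and Sln (38.6 ± 4.30), down to Nr2f2 at 6.84 ± 0.410. Conduction system markers were low, with a median of 1.98 TPM. Their highest members were Gja5 (4.74 ± 0.566), Cacna2d2 (4.71 ± 0.424), Tbx3 (3.44 ± 0.134) and the pacemaker channel gene Hcn4 (2.21 ± 0.417), and Isl1 was lowest at 0.270 ± 0.141.

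Among the other cells of the heart, fibroblast markers had the highest median, 53.9 TPM, led by Gsn (331 ± 33.2), Col3a1 (159 ± 10.6), Dcn (143 ± 9.98) and Col1a1 (69.0 ± 5.50), with Tcf21 lowest (4.24 ± 0.467). Endothelial markers followed at 26.8 TPM, led by Fabp4 (261 ± 33.7), Egfl7 (54.2 ± 1.07), Pecam1 (44.2 ± 1.72) and Cdh5 (43.1 ± 3.08), with Cldn5 lowest (12.1 ± 0.141). Macrophage markers had a median of 10.5 TPM, with Lyz2 at 62.7 ± 28.8, the complement gene C1qb at 17.4 ± 0.870, Csf1r at 14.4 ± 0.240 and Fcgr1 at 0.295 ± 0.134. Smooth muscle markers had a median of 10.2 TPM (Acta2 76.9 ± 17.6, Smtn 57.9 ± 6.02) and pericyte markers 8.63 TPM (Rgs5 93.0 ± 9.38, Abcc9 77.2 ± 0.516). Endocardial (median 6.61 TPM, Npr3 12.8 ± 1.22), lymphatic (3.57 TPM, Prox1 16.5 ± 1.36) and epicardial lists (3.39 TPM, Upk3b 11.9 ± 2.20, Msln 10.9 ± 0.955) were lower. The order of the list medians depends on the genes chosen and on the unit, so it does not rank amounts of cells.

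Markers of circulating cells went different ways. The erythroid list had a median of 840 TPM, with Hba-a2 at 9911 ± 4872 and Hbb-bt at 1527 ± 638, and the platelet list 2.22 TPM, with Pf4 at 17.9 ± 5.41. T cell, B cell and neutrophil lists had medians of 0.115, 0.485 and 0.268 TPM, with Cd2 at 0.350 ± 0.0849, Ighm at 4.68 ± 0.396 and Csf3r at 0.355 ± 0.0778 as their highest members. Lists for tissues next to the heart or far from it were low, with medians of 0.170 TPM for lung, 0.0050 for thymus, 0.118 for skeletal muscle, 0.0750 for liver and 0.0550 for cartilage. The lung median was 0.060 in replicate 1 and 0.215 in replicate 2, the liver median 0.120 and 0.030, and the neutrophil median 0.160 and 0.255. Single members stood above their lists, namely the transferrin gene Trf of the liver list at 24.5 ± 10.6 TPM, Comp of the cartilage list at 2.42 ± 0.0919 and the fast muscle genes Tnni2 and Mylpf at 1.39 ± 0.255 and 1.25 ± 0.290. Ly6g, Foxn1, Rag2, Fgb, Matn3 and Myog had a count of 0 in both hearts. Schwann cell and neuron markers had a median of 0.615 TPM, and the adipocyte list had a median of 9.58 TPM, with medians of 14.8 in replicate 1 and 3.72 in replicate 2.

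**Figure D2:**
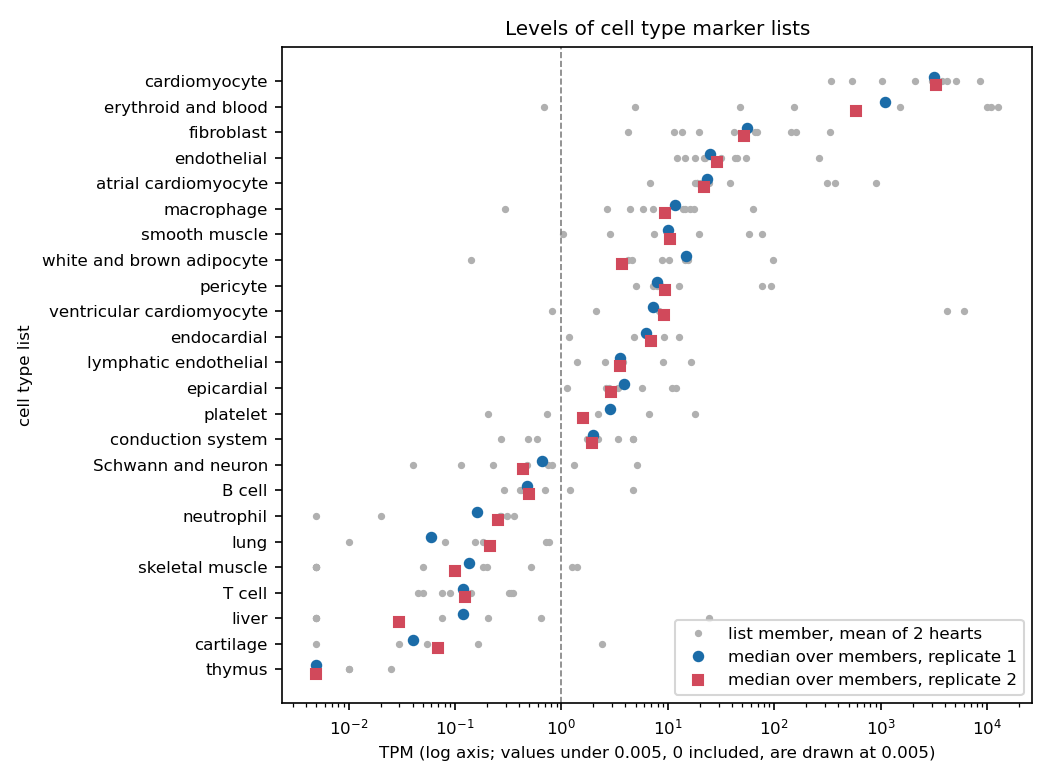
TPM of 24 cell type marker lists on a log axis, with members as grey points (mean of both hearts) and the median over members in replicate 1 (circles) and replicate 2 (squares); the dashed line marks 1 TPM. Heart muscle markers are highest, with a median of 3218 TPM, thymus markers are lowest, and among lists above 1 TPM the adipocyte, erythroid and platelet medians stand farthest apart between the hearts; the lung and liver medians, near 0, do so too.

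Gene groups of heart muscle function were expressed throughout. All 20 sarcomere genes reached a TPM of 1 in both hearts, from the tropomyosin gene Tpm1 (4397 ± 390) among the highest to Nexn (118 ± 2.06), with a list median of 718 TPM. All 17 calcium handling and channel genes did so, with a median of 127 TPM, led by Atp2a2, phospholamban Pln (2092 ± 96.1) and Casq2 (350 ± 60.3), with the potassium channel gene Kcnd2 lowest. Nuclear genes of oxidative phosphorylation had a median of 722 TPM, with Atp5b (3376 ± 72.9), Cox4i1 (1676 ± 10.8), Atp5a1 (1116 ± 538) and Ndufa4 (1100 ± 32.3) highest and Cycs (57.3 ± 6.46) lowest. Fatty acid oxidation genes had a median of 392 TPM, led by the fatty acid carrier Fabp3 (1782 ± 119), the lipoprotein lipase gene Lpl (1055 ± 42.0), Hadhb (628 ± 19.3) and Cd36 (537 ± 0.332). Glycolysis genes had a median of 304 TPM, with Gapdh (1641 ± 129), Aldoa (1202 ± 33.4), Ldhb (926 ± 32.7) and Eno3 (707 ± 68.1) highest. The fetal and stress list had a median of 144 TPM, with Nppa, Myh7, Myl4 and Myl7 highest and Tnni1 lowest. Nppa, Myl4 and Myl7 are also members of the atrial list, so atrial tissue in the samples may enter their levels.

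Regulatory genes were lower. Cardiac transcription factors had a median of 29.7 TPM, led by the coactivator gene Ppargc1a (68.7 ± 30.1), Esrra (55.1 ± 0.940), Mef2a (46.2 ± 0.191) and Mef2d (39.5 ± 0.509), and Hand1 had a count of 0. Of 19 cell cycle genes, 8 reached a TPM of 1 in both hearts, led by Pcna (13.4 ± 0.0636) and the replication genes Mcm2 (2.44 ± 0.290), Mcm6 (2.04 ± 0.375) and Mcm3 (1.71 ± 0.0566), with the mitotic kinase gene Bub1 lowest (0.135 ± 0.0354). Matrix genes had a median of 60.8 TPM, led by Sparc (274 ± 9.17) and the basement membrane collagens Col4a1 (184 ± 10.8) and, after Col3a1, Col4a2 (99.4 ± 7.38). Heat shock genes were led by the constitutive Hspa8 (431 ± 16.4) and Hspb1 (135 ± 4.47), and the inducible Hspa1b was lowest (1.20 ± 0.714). Among immediate early genes, with a median of 2.48 TPM, Jun (20.9 ± 8.81) and Dusp1 (17.0 ± 1.42) were highest and Fosb (0.160 ± 0.0707) lowest. Clock genes had a median of 5.78 TPM (Tef 25.1 ± 3.10, Nr1d1 21.2 ± 0.912), and imprinted genes 5.34 TPM, led by Igf2 (52.9 ± 4.29), Snrpn (41.6 ± 4.73), Igf2r (36.6 ± 1.73) and Grb10 (35.3 ± 2.25). Of the noncoding RNAs, Rpph1 (4238 ± 57.6), Malat1 (1313 ± 70.7) and Rmrp (1102 ± 47.5) followed Rn7sk. The median of this list was 21.3 TPM in the first quantification and 1.87 in the second.

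The share of each gene's most abundant transcript was measured in 14 genes, which include sarcomere genes, calcium handling genes, transcription factor genes and the pyruvate kinase gene Pkm. The same transcript led in both hearts for 14 of 14, and it held over 50% in both hearts for 8. Shares were highest for Tpm1-205 (96.5% ± 0.164), Actn2-201 (93.4% ± 2.19), Ryr2-201 (78.5% ± 1.88), Ldb3-203 (69.1% ± 0.523) and the Tnnt2 transcript ENSMUST00000189355.6 (63.8% ± 2.35). Pdlim5-205 held 55.7% ± 0.335 and Mef2d-201 held 50.2% ± 1.19. Several genes were split between a pair of transcripts. Tnni3-201 held 51.3% ± 0.697 and Tnni3-202 held 47.3% ± 0.828, Pkm-202 held 51.2% ± 0.874 and Pkm-201 held 47.3% ± 1.12, and Ttn-201 held 35.5% ± 0.916 and Ttn-215 held 31.1% ± 1.25 of titin transcripts. Camk2d-202 (47.7% ± 0.662), Myh6-201 (43.1% ± 0.772), Slc8a1-202 (39.4% ± 3.14) and Mef2c-217 (21.7% ± 1.71) led without reaching 50%. The second quantification named the same leading transcript for 10 of the 14 genes and put over 50% on it for 5. It gave most of Tnni3 to Tnni3-204 (48.5%) and Tnni3-201 (44.1%), and put Pkm-201 (47.7%) above Pkm-202 (44.4%). It gave that Tnnt2 transcript almost nothing (2.0e-04%) and Tnnt2-209 43.0%, and it gave Slc8a1-202 8.61% and Pdlim5-205 34.4%, where the leading Pdlim5 transcript differed between the hearts, so the shares within these genes are uncertain.

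**Figure D3:**
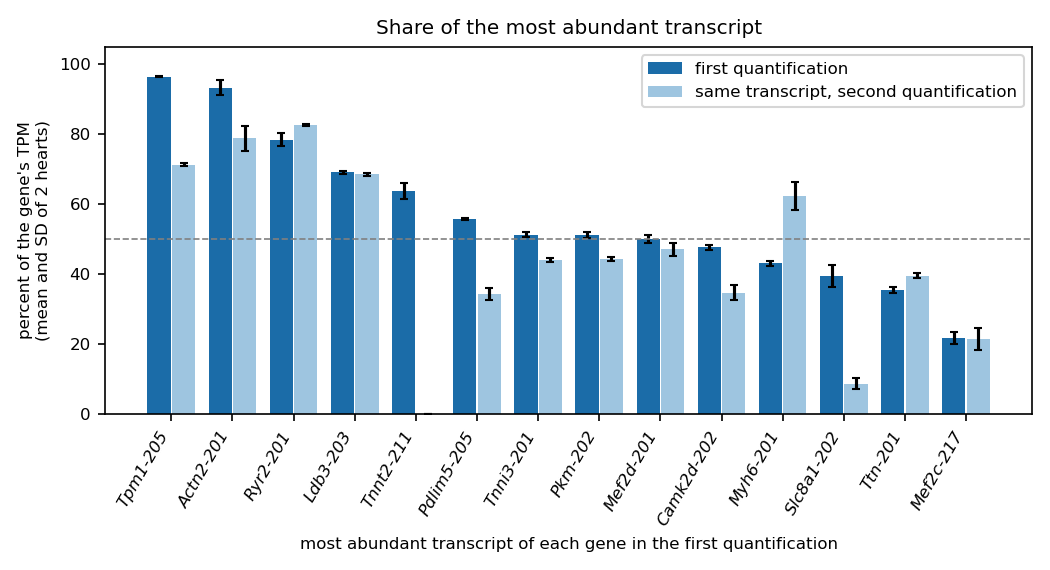
Percent of a gene's transcript TPM held by the transcript that leads in the first quantification (dark bars), and by that transcript in the second quantification (light bars), as mean and SD of both hearts; the dashed line marks 50%. Tpm1-205 holds 96.5% in the first and 71.3% in the second, and the leading Tnnt2 transcript 63.8% in the first and almost nothing in the second.

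The 2 hearts were then compared with each other, to describe the spread within the group. Adipocyte, platelet and red cell genes were lower in replicate 2, with the list medians farthest from 0. Cfd (ENSMUSG00000061780.6, chromosome 10, 79890853 to 79892655), which encodes the adipocyte protein adipsin, stood at 174 TPM in replicate 1 and 22.1 in replicate 2, a log2 ratio (replicate 2 over replicate 1) of -3.02 (95% interval -3.14 to -2.90). Adiponectin, Adipoq (ENSMUSG00000022878.5, chromosome 16, 23146536 to 23158028), stood at 25.0 and 4.05 TPM (-2.78, interval -3.06 to -2.51). Other genes of secreted and immune proteins were also among the 10 with the largest ratios toward replicate 1, namely Cd5l (-3.52), the protease inhibitor Slpi (-3.13), the chemokine Cxcl13 (-2.81), haptoglobin Hp (-2.74) and the lipoxygenase Alox15 (-2.67). The others were the gene models Gm45837, Gm10335 and Gm4332, the first 2 with counts of 0 in replicate 2 and at least 69.5-fold and 30.4-fold lower there at the floor of 3 counts (upper 95% limits of the log2 ratio -5.80 and -4.60). Gm45837 overlaps Arap1 and Pde2a and had a log2 ratio of 0.97 in the second quantification, the opposite direction, so its ratio is uncertain. Gm4332 is a pseudogene with a log2 ratio of -3.03 and no counts in either heart in the second quantification, which gave Gm10335 0 counts in replicate 1 and 3.10 in replicate 2, so both ratios are uncertain.

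Among the 10 largest ratios toward replicate 2 were several gene models that overlap others. The 10 were 1700047I17Rik2 and Tmem254c, whose counts rounded to 0 in replicate 1 and which were at least 54.7-fold and 28.9-fold higher in replicate 2 at the floor of 3 counts (lower 95% limits of the log2 ratio 5.46 and 4.52), Pagr1a (log2 ratio 4.46), the Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4 copies of U3 small nucleolar RNA on chromosome 11 (2.95 for each), the histone gene Hist2h2aa1 (2.40), Eps8l1 (2.16) and the pseudogene Gm13394 (1.97). In the second quantification Tmem254c had 0.04 and Hist2h2aa1 0.11, while Eps8l1 had 2.12 and Pagr1a 5.19. It gave almost no counts to 1700047I17Rik2 and none to these Rnu3b copies in either heart. The models that overlap these Rnu3b copies and carry the same symbols had -1.72, so the ratios are uncertain. Pagr1a overlaps the models Pagr1b and Gm42742 and had only 4 counts in replicate 1 and 90 in replicate 2. Its ratio (interval 2.95 to 6.26) is therefore uncertain too, although both quantifications put it higher in replicate 2. In all, 38 genes were 2-fold or more higher in replicate 2 and 116 in replicate 1, of 12911 compared, and 16 and 86 of them were so in both quantifications, a count chosen after seeing the data. Scaled by spike-ins, which moved the median of all genes to -0.14, the counts were 26 and 173, and the share of these genes that were higher in replicate 2 went from 24.7% to 13.1%. The median absolute log2 ratio was 0.12 and the biological coefficient of variation 10.9%.

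**Figure D4:**
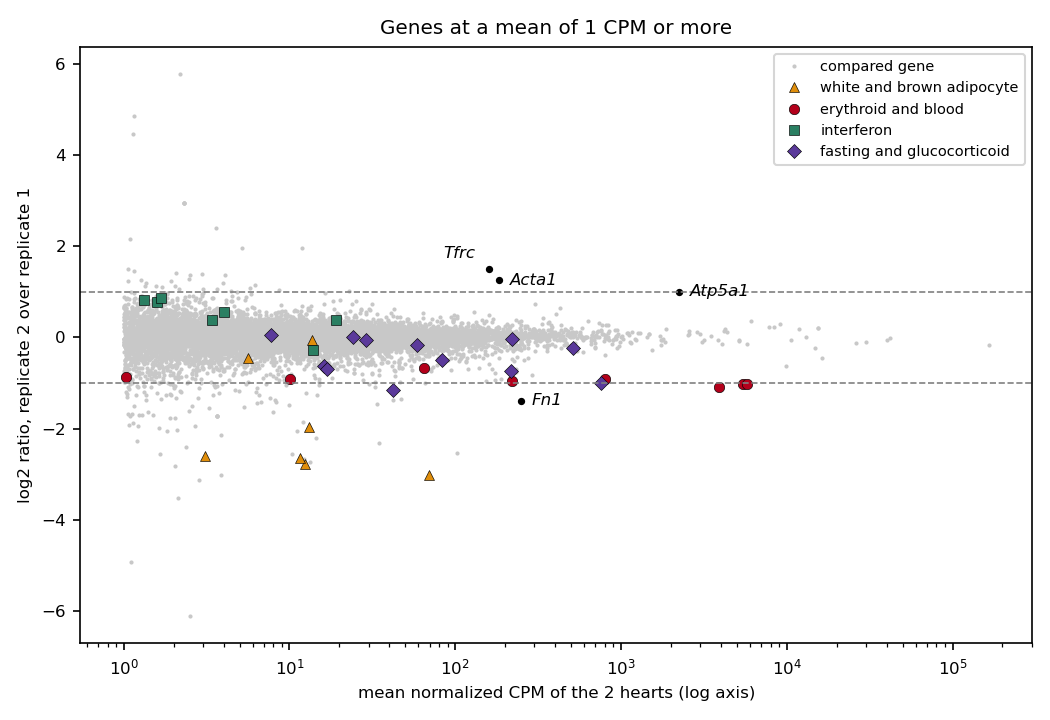
Log2 ratio of normalized CPM, replicate 2 over replicate 1, against the mean CPM of both hearts on a log axis, for 12911 genes (grey), with members of 4 lists in colour; dashed lines mark 2-fold. Adipocyte genes such as Cfd (-3.02) and the hemoglobin genes (Hbb-bs, -1.03) lie below most genes; Atp5a1 is at 0.99, Acta1 at 1.25, Fn1 at -1.40 and Tfrc, chosen after its value was seen, at 1.51.

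Of 34 lists with at least 3 members past the filter, 15 had a median log2 ratio outside the central 95% of random lists, against 5% by chance for unrelated lists. The medians of 12 of these were toward replicate 1. All 7 adipocyte members lay below 0, with a median of -2.61, and 5 of them differed 2-fold or more. Beside Cfd and Adipoq these included Cidec (-2.64) and Retn (-2.61), while the brown fat gene Cidea, at 15.6 ± 0.0990 TPM, had -0.05. All 8 erythroid members lay below 0, with a median of -0.94. They included Hba-a2 (-1.08, interval -1.09 to -1.07), Hbb-bs (-1.03, interval -1.04 to -1.02) and Hba-a1 (-1.01), of which Hbb-bs and Hba-a1 fell short of 2-fold with library totals, at -0.98 and -0.96. The platelet median was -0.97, from 3 members, with Itga2b at -1.17 (interval -1.49 to -0.86). Macrophage markers had a median of -0.25, with Lyz2 at -1.01 (under 2-fold with DESeq2 size factors or library totals, at -0.999 and -0.95), and fibroblast (-0.19), epicardial (-0.26), lymphatic (-0.29), smooth muscle (-0.18) and atrial (-0.12) markers also lay outside toward replicate 1. Members of some lists went both ways, with 2 of 6 lymphatic markers (Flt4 at 0.27 and Prox1 at 0.13) and 3 of 7 smooth muscle markers above 0. The smooth muscle median was 0.01 at a mean of 5 CPM or more. Pericyte markers lay outside toward replicate 2, with a median of 0.16.

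Genes that respond to fasting and glucocorticoids were lower in replicate 2 in 11 of 12 cases, with a median of -0.37. Pdk4, which restrains glucose oxidation, stood at 501 and 250 TPM (2.01-fold lower in replicate 2, and just under 2-fold with DESeq2 size factors, library totals or the second quantification), and Fkbp5, a glucocorticoid target, at 22.4 and 11.8 TPM (-1.14, interval -1.25 to -1.04). Immediate early genes had a median of -0.30, with 13 of 15 below 0. Clock genes had a median of -0.12, with 10 of 16 below 0 and 6 above, and with Per2 at -1.53 (interval -1.86 to -1.22). The interferon list lay outside toward replicate 2, with 6 of 7 members above 0 and a median of 0.57, including Bst2 at 0.57 (interval 0.23 to 0.90). Mitochondrially encoded genes had a median of 0.10, outside toward replicate 2, with 9 of 15 members above 0 and 6 below, while their summed share of gene counts was lower in replicate 2 (31.7% in replicate 1 and 31.0% in replicate 2). Spike-in scaling lowered the ratios of all genes alike, which put this median at -0.0392, still outside the central range of random lists. Inside the central range were the sarcomere (0.07, with 15 of 20 members above 0), calcium handling (0.08, 13 of 17), fatty acid oxidation (0.02, 13 of 16) and glycolysis (0.08, 13 of 13) lists. Also inside were the nuclear oxidative phosphorylation (0.02, 12 of 19), matrix (-0.0040, 8 of 16), imprinted (0.05, 11 of 19), cell cycle (0.03, 8 of 11) and heat shock (-0.09, 4 of 11) lists. So were the heart muscle cell (0.04), ventricular (0.13), conduction (0.01), endothelial (0.08), endocardial (0.07), B cell (-0.20), Schwann cell (-0.38), fetal and stress (-0.06), cardiac transcription factor (0.04) and noncoding RNA (-0.05) lists. Some of these lay outside under other settings, namely Schwann cell markers in the second quantification (-0.49) and at 0.1 CPM (-0.81), the fetal and stress list at 0.1 CPM (-0.12), the cell cycle list in the second quantification (0.18), and the conduction (0.18) and calcium handling (0.08) lists at 5 CPM. Single members of these and other lists still differed 2-fold or more. Skeletal actin Acta1 was higher in replicate 2 (1.25, interval 1.20 to 1.30), and fibronectin Fn1 (-1.40, interval -1.44 to -1.35), the paternally expressed Nnat (-2.56, interval -3.33 to -1.86), and Hspa1b (-1.32, interval -1.76 to -0.90) were lower. These differences have no replicate check.

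**Figure D5:**
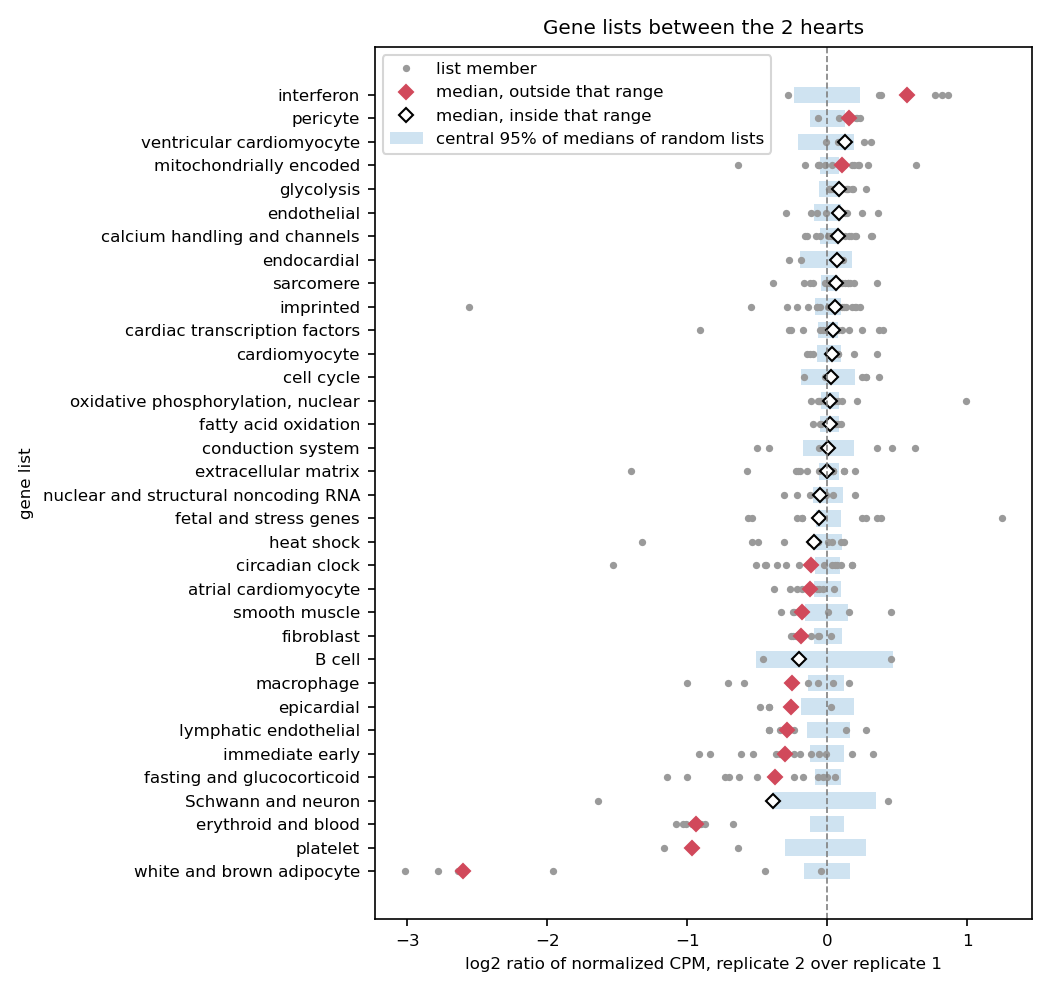
Log2 ratio of normalized CPM, replicate 2 over replicate 1, for 34 gene lists, with members as grey points, medians as diamonds and the central 95% of medians of random lists as bars. The adipocyte (-2.61), platelet (-0.97) and erythroid (-0.94) medians lie farthest below 0 and the interferon median (0.57) farthest above, while muscle and energy lists lie near 0.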

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

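Counting only genes past 2-fold in both quantifications, adding pseudogenes to the mitochondrial share, and leaving out list members in turn were chosen after seeing the data. The first member was higher in 18 of 18 pairs under every alternative, and 33 to 34 lists had a median level of 1 or more. The ratio moved by over 1.5-fold for 6 pairs in CPM, among them Myh6 over Myh7 (4.75) and Pgam2 over Pgam1 (2.01), for 4 in the second quantification and for 1 at a pseudocount of 1. List levels moved by more than the SD between hearts for 36 of 43 lists in CPM, which is a different unit, for 31 in the second quantification and for 39 of 42 over nuclear genes alone. In the second quantification the erythroid median was 1956 TPM, and the noncoding RNA median went from 21.3 to 1.87 TPM. The pericyte median was 52.1 CPM, above that of smooth muscle (36.9) and macrophage markers (13.9). Genes at the TPM threshold in both hearts were 7366 at a TPM of 5, and 12126 to 12157 with either heart left out, when 1 heart alone has to pass. Genes higher in replicate 2 and in replicate 1 were 842 and 1279 with no filter, 8 and 41 at a mean of 5 CPM, 205 and 383 at 1.5-fold, 11 and 45 at 3-fold, and 16 and 86 in both quantifications, as fewer or more genes pass by construction. Lists outside the central range were 14 to 18 under the alternatives, and the platelet and interferon lists had too few members at 5 CPM. The median of mitochondrially encoded genes was -0.0392 with spike-in scaling, which by construction lowered all genes alike, and it stayed outside the central range. The median of smooth muscle markers was 0.00849 at 5 CPM, and the log2 ratio of Gm45837 was 0.97 in the second quantification, both the opposite direction, and the cause was not tested. The coefficient of variation between hearts was 0.10853 with DESeq2 size factors, 0.0985 at 5 CPM and 0.112 at 0.1 CPM. The median gene-wise DESeq2 estimate was 0.0001, its lower bound, and the cause was not tested. The mitochondrial share was 34.6% with the pseudogenes and 31.0 to 31.7% with either heart left out. The spike-in share was 0.801% of TPM, where length enters, and 0.505 to 0.577% of counts with either heart left out. Genes with a transcript over 50% were 5 in the second quantification, for which the cause was not tested, and 8 to 9 with either heart left out. No paired analysis was possible because the series has 1 group. A difference between these hearts has no replicate test, and depth limits genes near the floor of 3 counts.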

Other observations

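The genes of this paragraph were chosen after their values were seen, and are given as log2 ratios of replicate 2 over replicate 1. Higher in replicate 2 were the transferrin receptor gene Tfrc (1.51, 25.6 and 69.3 TPM), the macrophage receptor gene Cx3cr1 (1.37), the immunoproteasome gene Psmb9 (1.19) and the interferon-induced Gbp3 (0.94) and Gbp4 (0.91). Lower in replicate 2 were Car3, a carbonic anhydrase abundant in fat (-2.53, 128 and 22.9 TPM), Pck1 (-2.32), Prg4 (-2.21), the coagulation factor gene F5 (-2.06), the adipocyte transcription factor gene Cebpa (-1.41) and the complement gene C4b (-1.35). Among genes of insulin and glucocorticoid response, Irs2 had -1.01 and Klf15 -0.99. Tmem254b had -2.40, opposite to Tmem254c.

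The tests with a second adipocyte list, a second erythroid list and the neighbours of Atp5a1 were written before the values they measure were seen. The other 5 tests, on 4 lists of other cells, on scaling, on summed globins, on overlapping models and on ATP synthase subunits, were chosen after the result was seen. So was the measure of spread used for each, which is the SD of list members, or 0.222 for a single ratio. The SD of members describes the genes and is not the error of their median. The design has 1 group, so it names no biological difference to test as an explanation.

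Adipocyte genes were lower in replicate 2, with a median of -2.61. Scaling moves all genes alike, and the median of all genes lay only from -0.14 to 0.06 over the 4 scalings tried. The highest adipocyte median over them, -2.55, was bound to stay low, so the choice among these scalings does not account for the pattern. Of 4 lists of other cells, the endothelial (0.08) and pericyte (0.16) medians lay above 0 and the fibroblast (-0.19) and smooth muscle (-0.18) medians below. A loss of all 4 kinds alike is argued against, but a loss of some kinds is not. Different amounts of adipose tissue in the samples may account for the lower adipocyte genes. However, a second adipocyte list had a median of only -0.45, where a median above -0.5 had been set beforehand as speaking against this. It lay past that bound by less than the SD of its members, 0.317, a criterion added after the value was seen, so adipose amount stays open. The median of the second list was at percentile 0 of random lists, so this list moved toward replicate 1, though by far less than the first. Of its 12 genes 10 passed the filter and 9 lay below 0, and the heart expressed several at a high level, such as Dgat2 at 106 and 97.3 TPM. Slc7a10 (1.45 and 0.28 TPM in replicates 1 and 2) and Orm1 (1.22 and 0.41 TPM) did not pass and do not enter the median. In the second quantification their log2 ratios were -1.96 and -1.39, from low levels.

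Erythroid genes were lower in replicate 2, with a median of -0.94. Reads shared between globin copies are argued against, since all 4 copies were lower, from -1.08 to -0.91. Their summed count, at -1.03, had to follow from these. Different amounts of blood left in the samples may account for the lower erythroid genes. A second erythroid list had a median of -0.64, at percentile 1.05 of random lists and past the bound of -0.5 set beforehand in favour. It passed the bound by less than the SD of 0.507 and from 3 of 12 genes, so this stays open.

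Atp5a1, a subunit gene of mitochondrial ATP synthase, was chosen after its values were seen, at 736 TPM in replicate 1 and 1497 in replicate 2 (log2 ratio 0.99, just under 2-fold). Overlapping models or the choice of quantification are argued against, with a lowest log2 ratio of 0.98. A difference spanning the region is argued against, with a median of 0.0103 over 7 expressed neighbours within 1 Mb. The neighbours could not show a change confined to Atp5a1. A shift of all subunits is argued against, with a median of 0.0308 over 14 others. Both animals are F1 hybrids of the same cross, so inherited alleles of this gene on chromosome 18 should not differ between them. Another difference specific to this gene in 1 of the animals could remain and was not tested.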
